A study of Mus musculus with 6 samples.

How the data were processed

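Total RNA of 6 samples of the mouse 266.6 line, 3 exposed to fibroblast-conditioned medium and 3 controls, was sequenced after library preparation with an Illumina TruSeq kit, per the labels' protocols. The submitters' processing notes name FastQC, DESeq2 and the human build hg19. The gene symbols are those of mouse, and the aligner, the counting program and the mouse build were not given in the sources used here, so no coordinates are printed. Symbols are written as in the table, where a full stop replaces a hyphen.

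The deposited table holds 1 value per gene and library as a signal that is never negative: read counts that had been divided by 1 factor per library, normalized by the authors before deposit. In each library 100% of the values are whole multiples, within 0.001 of a read, of a value between 0.949 and 1.05, the worth of 1 read there. Reads were recovered by this division, 19953198, 19031271 and 18622370 in control replicates 1, 2 and 3 and 19517839, 20368257 and 21002226 in the CAF_CM replicates. The lowest total of any row over the 6 libraries is 10 reads, so rarer genes have no row. Of 20764 rows, 168 carry no gene symbol and stayed out of the tests. They took between 0.153% and 0.261% of the reads of a library.

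The design fixed before the data were examined assumed raw counts and edgeR's quasi-likelihood test. Because the values are normalized, the main test was instead limma 3.58.1 (R 4.3.3) on log2(value + 1), with a variance trend in the empirical Bayes step, over genes with a value of at least 10 in at least 3 libraries, and Benjamini-Hochberg adjustment with a threshold of 0.05. The pseudocount and this filter were chosen after a first look at the values. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. The planned edgeR test (version 4.0.16, TMM) was run on the recovered reads as an alternative, with limma's gene filter in place of edgeR's planned default filter. Over the same genes as limma it called 5570, of which 5466 were shared in the same direction with the 5555 of limma.

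29 gene lists were fixed before the data were examined: acinar enzymes, acinar regulators, ductal and metaplasia genes, epithelial junction, mesenchymal genes, laminins, integrins, focal adhesion, other matrix genes, the IL6, JAK and STAT3 pathway, RAS and MAPK output, TGF-beta, Wnt, Notch, YAP and TEAD, cell cycle, unfolded protein response, interferon, inflammation, hypoxia and glycolysis, cholesterol synthesis, stemness, p53 and growth arrest, immediate early and heat shock genes, markers of fibroblasts, immune, endothelial and islet cells, and mitochondrially encoded genes. Members were matched by symbol or, failing that, by a RefSeq synonym. The list of mitochondrially encoded genes had 0 members tested and was not analysed here, which left 28 lists. Each was tested by camera with a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 28 lists, and again with an estimated correlation and by fry. Camera was planned on limma-voom's log2 CPM and was run on log2(value + 1). No list was called by camera with an estimated correlation. Fry, which does not compare a list with other genes, called 8 lists in 1 direction. Besides these, the count of members past the threshold is given over all genes tested and adjusted over the list alone.

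Genes named in the text follow a rule fixed beforehand: the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between groups, leaving out predicted genes and pseudogenes; 8 genes named in advance; up to 3 called members of each list by lowest adjusted p, or 2 where none was called; and the 3 genes of highest mean. Further list members named beside them were chosen after their values were seen. Some genes, including 1 that the rule names, are not reported here.

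Alternatives changed 1 choice at a time: edgeR with DESeq2's size factors, library totals, DESeq2 1.42.0, limma-voom, no filter, a filter of 1 CPM, the replicate number as a block, and each library left out in turn. Added after seeing the data were pseudocounts of 0.5 and 5, TMM scaling, separate weights for the groups, the planned edgeR test as run on recovered reads, and a spline correction of each library for transcript length and GC content. Length and GC content came from the longest GENCODE transcript of each symbol, found for 97.5% of the genes tested. The variation between libraries was measured as edgeR's common biological coefficient of variation within each group.

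The test was checked on simulated counts for this comparison, with 200 changed genes among 16264 tested. The counts were drawn with the control means, the real library sizes and a common variation within each group. It called 100% of the genes raised or lowered by 1 log2 unit, 82% of those raised and 82% of those lowered by 0.5, and 9 of 16064 unchanged genes. Genes were drawn independently and the changed ones were not low. The simulation therefore lacks the gene-by-gene variation and shared shifts of real libraries, and its rates need not hold for them.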

Results

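RNA sequencing compared 266.6 cells, a mouse pancreatic acinar tumour line, under culture with medium conditioned by cancer-associated fibroblasts (CAF_CM, exposure of up to 40 days) with the same line as control. Each group held 3 libraries. The reads behind the deposited values came to between 18622370 and 21002226 per library, and 16169 genes were tested. Across genes, the Spearman correlation was 0.998 between control libraries, 0.994 to 0.996 between CAF_CM libraries and 0.990 to 0.991 between libraries of different groups. The first principal component held 55.1% of the variance and separated the groups. The biological coefficient of variation was 2.20% among control and 8.23% among CAF_CM libraries, so the treated libraries varied 3.74 times as much. By pair, it was 6.68% for CAF_CM replicates 2 and 3, 7.53% for replicates 1 and 3 and 10.2% for replicates 1 and 2. Among control pairs it was 1.19% for replicates 2 and 3, 2.29% for replicates 1 and 2 and 2.76% for replicates 1 and 3. The labels do not say that replicates came from separate cultures, and the p-values of single genes therefore measure the spread between these libraries, which may be technical. Limma fitted a shared variance per gene to both groups, although their spread differed. Camera's p-values compare a list with the other genes, and with the preset correlation they treat its members as nearly independent.

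The comparison asks which genes differ between acinar tumour cells kept in fibroblast-conditioned medium and control cells. A time is recorded here for the CAF_CM libraries only, so effects of the medium and of time in culture cannot be told apart. Among called genes with a mean of at least 5 CPM in the higher group and no overlap between groups, the largest rise was that of Neurod1, a transcription factor of neuronal and endocrine differentiation, which went from 54.5 ± 3.30 to 233 ± 57.7 normalized counts (mean ± SD, n = 3 per group here and throughout), a log2 fold change of 2.05, SE 0.17. Tubb3, a tubulin typical of neurons, rose 3.19-fold from 268 ± 26.7 to 862 ± 149 normalized counts. The neuronal guidance factor Draxin rose 2.89-fold, the synaptic vesicle calcium sensor Syt1 2.78-fold, the calcium-binding protein Hpca 2.40-fold, Fam163a 2.68-fold, Glipr2 2.52-fold and H2.T24 2.36-fold. Under the same conditions, the largest falls were those of Kctd14 (3.71-fold lower) and of albumin, Alb, which went from 184 ± 7.42 to 60.5 ± 2.08 normalized counts. Apold1 was 2.89-fold lower, the glucose transporter gene Slc2a1 2.52-fold, the growth factor gene Bmp7 2.52-fold, the semaphorin and VEGF co-receptor gene Nrp2 2.42-fold, Clca3a1 2.34-fold and Cyba, a subunit of the NADPH oxidases, 2.34-fold. In limma with Benjamini-Hochberg adjustment, these 16 genes had adjusted p of 0.00642 or less, the highest being that of H2.T24, whose libraries spread from 58.7 to 145 normalized counts in CAF_CM.

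In all, 2953 genes were higher and 2602 lower in CAF_CM libraries at an adjusted p under 0.05 (limma). Most changes were small. The median absolute log2 fold change of the called genes was 0.34, and 72 genes rose and 263 fell by 2-fold or more. With library totals as the only scaling, the split was 2231 higher and 3179 lower. It moved the other way with the length and GC correction, to 3579 higher and 2487 lower among 15764 genes tested. Across genes, the log2 fold change had a Spearman correlation of 0.208 with transcript length. Without control replicate 1 the counts fell to 1868 higher and 1659 lower, without control replicate 2 to 1967 and 1715, and without control replicate 3 the lower genes numbered 1723. Genes at least 2-fold higher numbered 119 without CAF_CM replicate 1.

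**Figure D1:**
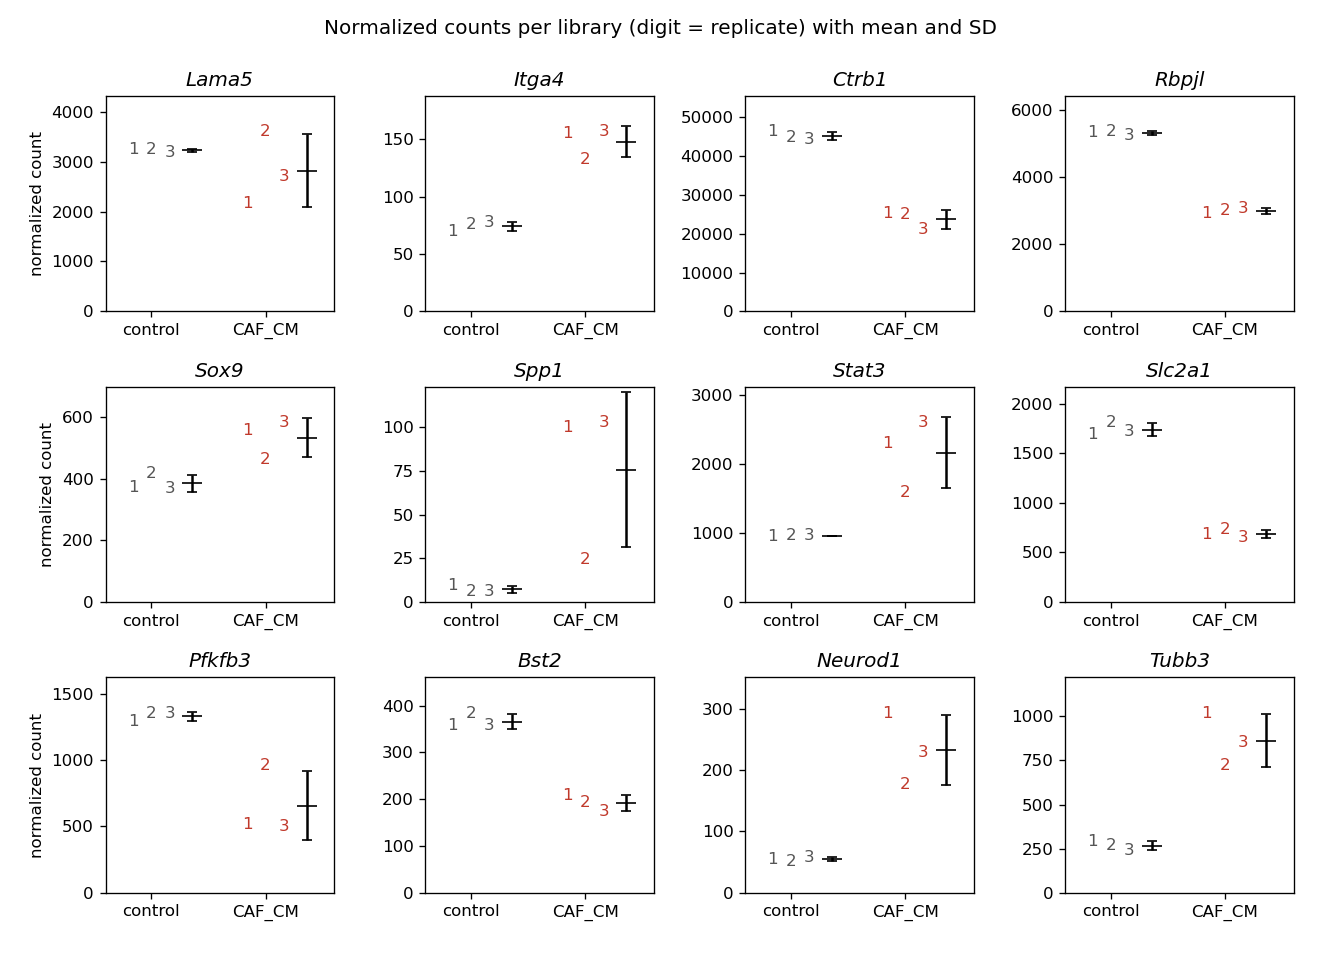
Normalized counts of 12 genes in each library (vertical axes from 0, one panel per gene), with digits for the replicates and a bar with whiskers for the mean and SD of 3 libraries. Itga4, Stat3, Neurod1 and Tubb3 lie higher in all CAF_CM libraries than in all controls, Ctrb1, Rbpjl, Slc2a1 and Bst2 lie lower, and the Lama5 values of CAF_CM libraries lie on both sides of the controls.

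The series title names laminin alpha 5 and integrin alpha 4. Itga4, the alpha subunit of integrins that bind fibronectin and VCAM1, rose 1.98-fold from 74.1 ± 4.23 to 148 ± 13.8 normalized counts (log2 fold change 0.99, SE 0.12, adjusted p = 1.90e-04). The values of Lama5, a laminin chain of basement membranes, were 3228 ± 30.4 normalized counts in control and 2822 ± 724 in CAF_CM libraries (log2 fold change -0.22, SE 0.13, 95% interval -0.52 to 0.0665, adjusted p = 0.216), and the CAF_CM libraries held 2162, 3597 and 2708. Among 6 laminin genes tested, Lamb1 rose (0.32), Lama4 fell (-0.34) and the others did not pass the test. Of 19 integrin genes, Itga4, Itga9 and Itgb8 rose, Itga2 fell (log2 fold change -0.90) and Itga5, Itgav and Itga2b also fell. Itgb1, the usual partner of alpha 4, had 5625 ± 52.1 normalized counts in control and 5426 ± 231 in CAF_CM libraries (adjusted p = 0.422). Focal adhesion genes gave 9 rises, among them the adaptor gene Parvb (0.48), the kinase gene Src (0.33) and Zyx (0.38), and 1 fall in 26 tested. In the list of other basement membrane and matrix genes, 7 of 25 fell, led by vitronectin, Vtn (from 13984 ± 225 to 9408 ± 701 normalized counts), the collagen prolyl hydroxylase gene P4ha2 (-0.69) and the lysyl hydroxylase gene Plod1 (-0.42), and Col4a2 rose.

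Adjusted over the list alone, 1 laminin rose and 2 fell, 4 integrins rose and 4 fell, 9 focal adhesion genes rose and 1 fell, and 1 matrix gene rose and 7 fell. By camera with a preset correlation, none of these lists differed from the other genes (adjusted p = 0.716 for laminins, 0.281 for integrins, 0.0759 for focal adhesion and 0.0843 for matrix). Without CAF_CM replicate 2, Lama5 was lower and past the threshold (-0.42, adjusted p = 0.00154), as it was after correction for transcript length and GC content (-0.38, adjusted p = 0.00171), and its adjusted p ran from 0.00154 to 0.671 over all alternatives. CAF_CM replicate 2 stood apart from replicates 1 and 3 in the mean log2 difference from control of the integrins (0.0743 against -0.30 and -0.16), laminins (0.20 against -0.36 and -0.20) and matrix genes (0.0349 against -0.18 and -0.28), and Itga2, Itga5 and Itga2b fell least there. The other basement membrane and matrix list was called lower without that library (adjusted p = 0.00173), in DESeq2 (0.0306) and after the length and GC correction (0.00202). The focal adhesion list was called higher without CAF_CM replicate 1 (adjusted p = 0.00762) and without a filter on low counts (0.0385). Lamb1 lost its call without CAF_CM replicate 3 (adjusted p = 0.0892), control replicate 1 (0.0881) or control replicate 2 (0.0698). Lama4 lost it without CAF_CM replicate 1 (adjusted p = 0.0681) or 3 (0.0664) and without control replicate 1, 2 or 3 (0.0655, 0.144 and 0.0785), and Itga5 without control replicate 1 (0.0519).

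Genes for acinar digestive enzymes fell as a list by camera with a preset correlation, a call that was lost with an estimated correlation (adjusted p = 0.518). Of 27 tested, 14 fell and none rose. Ctrb1, which encodes chymotrypsinogen B, fell 1.91-fold from 45083 ± 997 to 23668 ± 2338 normalized counts, and the elastase gene Cela1 fell 1.73-fold from 12701 ± 230.3 to 7384 ± 958 normalized counts. Amy1 was 2.10-fold lower, Reg1 (-0.72) and Pnliprp1 (-0.69) fell, and Amy2a1 to Amy2a5 also fell, although these near-identical copies share reads and their separate values are uncertain. The copies enter the 14 falls and the list tests as separate members, so both may count the same signal more than once. Cpa1, the carboxypeptidase A1 gene, had 2062 ± 56.1 normalized counts in control and 2279.5 ± 515 in CAF_CM libraries (log2 fold change 0.12, SE 0.12, adjusted p = 0.470). Among 17 regulators and secretory genes of acinar cells, Rbpjl, a subunit of the acinar transcription complex PTF1, fell 1.77-fold from 5316 ± 53.4 to 2996 ± 79.7 normalized counts, whereas the genes that rose included Rab3d (0.32), Nr5a2 (0.22) and Gata4 (0.16), and Foxa2 and Tfrc fell. Ptf1a, the DNA-binding subunit of that complex, had 753 ± 17.0 normalized counts in control and 841 ± 144 in CAF_CM libraries (adjusted p = 0.281), and Bhlha15, a regulator of secretory cell structure, 177 ± 6.05 normalized counts in control and 196 ± 20.0 in CAF_CM libraries (adjusted p = 0.326).

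Adjusted over the list alone, 1 enzyme gene rose and 15 fell, and 4 acinar regulators rose and 3 fell. Camera placed the enzyme list below the other genes (median log2 fold change -0.39, adjusted p = 1.25e-04) and did not call the regulators (median 0.15, adjusted p = 0.590). The value of Cpa1 was -0.0488 without CAF_CM replicate 2. Without that library Ptf1a passed the threshold (0.25, adjusted p = 0.0361), as it did after the length and GC correction (0.25, adjusted p = 0.0422).

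Ductal and metaplasia genes moved in both directions. Of 18 tested, 5 rose and 2 fell. Spp1, the osteopontin gene, rose from 7.34 ± 1.98 to 75.6 ± 44.3 normalized counts, with 24.5 in CAF_CM replicate 2. Sox9, a regulator of ductal cells, rose 1.38-fold from 385 ± 26.9 to 533 ± 63.5 normalized counts, Pdx1 rose by 0.31 and the liver and duct factors Onecut1 and Onecut2 by 0.77 and 0.44 log2 units. The hyaluronan receptor gene Cd44 (-0.52) and Clu (-0.28) fell, and Krt19 was not analysed here. Of 22 epithelial junction genes, the tight junction genes F11r (-0.43) and Tjp3 (-0.65), E-cadherin, Cdh1 (-0.64), and Spint2 fell, while Ocln and Esrp1 rose. Among 17 mesenchymal genes, Snai1 (0.78), Zeb1 (0.31), Zeb2 and Cald1 rose, and those that fell included Itga5 and Tgfbi.

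Counts adjusted over the list alone were the same for these 3 lists (5 and 2 ductal, 2 and 4 junction, 4 and 3 mesenchymal genes rose and fell). None of the 3 was called by camera (adjusted p = 0.312 for the ductal, 0.316 for the junction and 0.742 for the mesenchymal list). CAF_CM replicate 2 stood apart from replicates 1 and 3 in the mean log2 difference from control of the junction (0.14 against -0.18 and -0.15) and mesenchymal genes (0.12 against -0.0484 and -0.0160), with Cdh1 at 501 against 331 and 364 normalized counts and Tjp3 at 239 against 155 and 174.

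**Figure D2:**
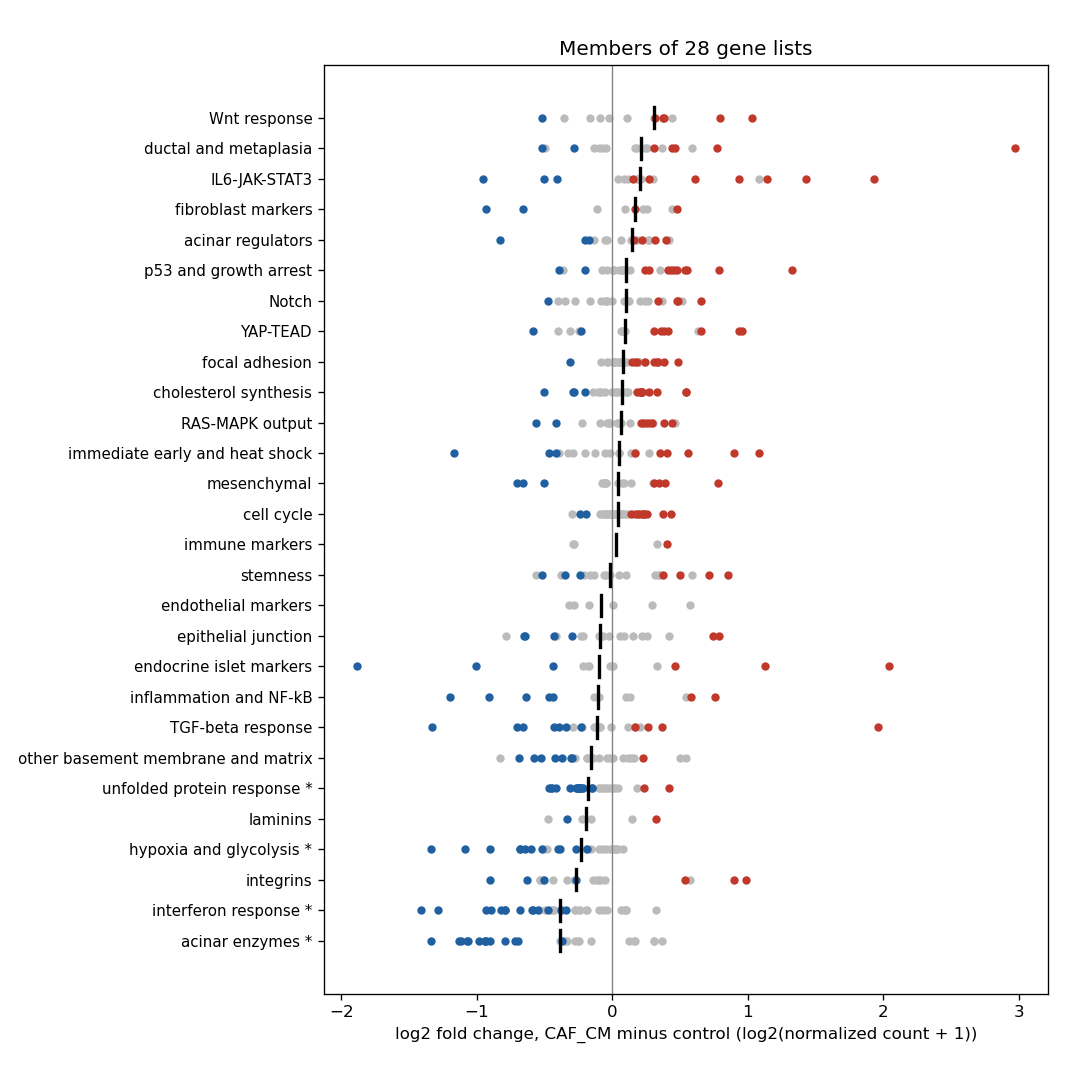
Log2 fold changes (CAF_CM minus control, horizontal axis) of the members of 28 gene lists, with red and blue points for genes higher or lower at an adjusted p under 0.05, grey points for the others, black bars for list medians and asterisks for the 4 lists called by camera with a preset correlation. The medians of those 4 lists lie between -0.39 and -0.18.

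Interferon response genes fell as a list by camera with a preset correlation, a call that was lost with an estimated correlation (adjusted p = 0.288). Of 35 tested, 14 fell and none rose. The antiviral membrane protein gene Bst2 fell 1.91-fold from 366 ± 15.3 to 192 ± 17.7 normalized counts. Other members that fell were B2m from 1830.0 ± 34.7 to 1223 ± 78.7 normalized counts and the class I heavy chain gene H2.D1 with a log2 fold change of -0.48, as did H2.K1, Tap1, Ifit1 and Usp18. Unfolded protein response genes fell in 16 of 28 cases, with the ubiquitin ligase gene Syvn1 (-0.45), Herpud1 (-0.41) and Sel1l (-0.31), all of the pathway that degrades misfolded proteins of the endoplasmic reticulum, and the chaperone gene Hspa5 (-0.15). The 2 genes of this list that rose were Asns and Sesn2, targets of the amino acid response. Hypoxia and glycolysis genes fell in 12 of 26 cases with no rise. Slc2a1 fell from 1738 ± 63.1 to 688 ± 42.1 normalized counts, Hk2, a kinase at the entry to glycolysis, and the stress gene Ndrg1 had log2 fold changes of -0.64 and -0.68, and Vegfa fell from 2648 ± 42.4 to 1779 ± 449 normalized counts.

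The list medians were -0.39 for interferon (camera adjusted p = 1.13e-04), -0.18 for the unfolded protein response (adjusted p = 5.97e-04) and -0.23 for hypoxia and glycolysis (adjusted p = 5.97e-04). With an estimated correlation the calls on the unfolded protein response and the hypoxia and glycolysis lists were lost too (adjusted p = 0.575 and 0.706). Adjusted over the list alone, 0 interferon genes rose and 14 fell, 3 unfolded protein response genes rose and 16 fell, and 0 hypoxia genes rose and 12 fell. CAF_CM replicate 2 stood apart in the hypoxia list, with a mean log2 difference from control of -0.0475 against -0.46 and -0.54 in replicates 1 and 3, and without it the list median was -0.35 (adjusted p = 8.57e-12). The hypoxia call was also lost without CAF_CM replicate 3 (adjusted p = 0.0610) and by fry (adjusted p = 0.120).

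**Figure D3:**
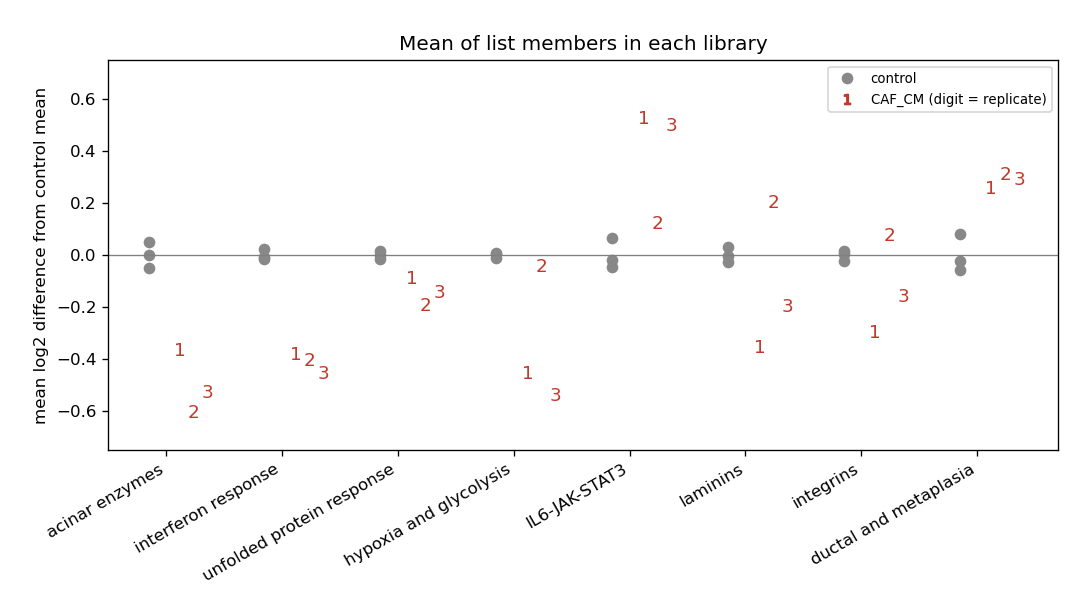
Mean log2 difference of the members of 8 lists from their control mean (vertical axis) in each library, with grey points for the 3 control libraries and red digits for the CAF_CM replicates. In the hypoxia and glycolysis list, replicate 2 lies at -0.0475 and the other replicates at -0.46 and -0.54, and in the laminin list replicate 2 lies above 0 and the others below.

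Genes of the IL6, JAK and STAT3 pathway included some of the stronger rises. Stat3 itself rose 2.21-fold from 956 ± 2.48 to 2162 ± 516 normalized counts, and its feedback inhibitor Socs3 rose 1.91-fold from 140.3 ± 8.95 to 275 ± 67.4 normalized counts. The oncostatin M receptor gene Osmr (1.93) and Lcn2 (1.43) rose from low levels, with smaller rises of Jak1, Jak2 and Cebpb, while the receptor genes Il11ra1 (-0.41) and Il6ra and the ligand gene Lif fell, which made 7 rises and 3 falls in 18 tested. CAF_CM replicate 2 was the lowest treated library for Stat3, at 1591 against 2299 and 2596, and the list mean was 0.12 there against 0.52 and 0.49. In the RAS and MAPK list, 7 of 21 rose, including the feedback inhibitor genes Spred2 (0.38) and Dusp4 (0.44), and the receptor genes Egfr (-0.42) and Erbb2 fell. Of 22 TGF-beta response genes, 4 rose and 7 fell, with Bmp7 at -1.33, the co-repressor gene Tgif1 at 1.96 and Skil at 0.36. Wnt response genes gave 5 rises, with Tcf7 (from 123 ± 5.13 to 255 ± 45.3 normalized counts) and the feedback gene Axin2 (0.80) foremost, and 1 fall, Cd44, in 13.

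Among 22 Notch genes, Rbpj (0.48), the transcription factor of the pathway, its ligand gene Jag1 (0.34), Notch3 and Dtx4 rose, and Dtx3 (-0.47) fell. Of 17 YAP and TEAD genes, 7 rose and 2 fell, with Wwc1 at 0.65, Tead2 at 0.36 and Fjx1 at -0.58. Inflammation genes gave 2 rises, Tnfaip2 (0.58) and Icam1, and 5 falls, including the NF-kB inhibitor gene Nfkbia (-0.44) and the cytokine gene Csf1 (-0.64), in 13 tested. Adjusted over the list alone, 8 IL6, JAK and STAT3 genes rose and 3 fell, 7 and 3 of the RAS list, 6 and 7 of the TGF-beta list, 6 and 1 of the Wnt list, 3 and 1 of the Notch list, 7 and 2 of the YAP list and 2 and 5 of the inflammation list. None of the 7 lists was called by camera, with adjusted p of 0.113, 0.299, 0.316, 0.281, 0.444, 0.281 and 0.312 in the order given. The IL6-JAK-STAT3 list was called higher without CAF_CM replicate 2 (adjusted p = 0.0116) and without a filter on low counts (adjusted p = 0.0187). Fry called the RAS-MAPK output list (adjusted p = 0.0205), the Wnt response list (0.00422) and the YAP-TEAD list (0.00422) higher and the inflammation and NF-kB list lower (0.0444), in which CAF_CM replicate 2 stood apart (mean log2 difference from control -0.30 against -0.0870 and -0.0489 in replicates 1 and 3).

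Mitotic genes were among the cell cycle genes that rose. Of 35 cell cycle genes, 10 rose and 2 fell. Kif11, a spindle motor, rose 1.35-fold from 3566 ± 83.4 to 4812 ± 209 normalized counts, the mitotic kinase gene Aurka by 0.37 and Ccnb1, the cyclin of mitotic entry, by 0.26 log2 units, while Ccne1 and E2f1 fell. Of 24 p53 and growth arrest genes, 10 rose and 2 fell, with the p53 targets Zmat3 (0.54), Trp53inp1 (0.47), Cdkn1a (0.55) and Eda2r (1.33) among the rises and the cyclin-dependent kinase inhibitor gene Cdkn1b (-0.40) and Plk2 among the falls. In the cholesterol list, 10 of 26 rose, including the enzyme genes Hmgcs1 (from 2634 ± 11.1 to 3839 ± 156 normalized counts) and Sqle (0.55), and those that fell included Ebp (-0.50), Nsdhl and Tm7sf2. Stemness genes gave 4 rises, among them Lin28a (0.72) and the intermediate filament gene Nes (0.50), and 3 falls, including Myc, in 21 tested.

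Of 21 immediate early and heat shock genes, 6 rose and 3 fell. The immediate early gene Egr1 fell 2.25-fold from 1175 ± 64.1 to 521 ± 18.6 normalized counts, and Dusp1 and Atf3 fell. Members that rose included the heat shock genes Hsp90aa1 (0.40) and Hspa1b (1.08), a near-identical copy of Hspa1a. Adjusted over the list alone, 10 and 2 cell cycle, 11 and 2 p53, 10 and 4 cholesterol, 4 and 3 stemness and 6 and 4 immediate early and heat shock genes rose and fell. Camera called none of these lists (adjusted p = 0.228, 0.0759, 0.281, 0.888 and 0.705), and the p53 and growth arrest list was called higher without CAF_CM replicate 2 (adjusted p = 0.0136), without control replicate 3 (adjusted p = 0.0414), without a filter on low counts (0.0212) and after correction for length and GC content (0.0403). Fry called the cell cycle list higher (adjusted p = 0.0205). The stemness list had a median of -0.0194 and a mean of 0.0712.

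None of the 4 lists of markers of other cell types was called. Of 9 fibroblast markers, Fbln1 (0.17) and Col1a2 rose, and Fbln2 (-0.66) and Dcn, the decorin gene, fell, the latter from 43.9 ± 7.40 to 23.0 ± 7.12 normalized counts. Among 4 immune markers, Coro1a rose by 0.41 log2 units, and no endothelial marker of 6 passed the test (Plvap -0.29, adjusted p = 0.0523, and Tek -0.32, adjusted p = 0.0580). Of 12 endocrine islet genes, 3 rose, the transcription factor genes Neurod1, Insm1 (0.47) and Nkx6.1 (1.13), and 3 fell, the granule protein gene Chga from 31229 ± 208 to 23040.0 ± 943 normalized counts, the prohormone convertase gene Pcsk2 from 451 ± 16.6 to 227 ± 38.8 normalized counts and Scg2 with a log2 fold change of -1.89. Adjusted over the list alone, 2 and 2 fibroblast, 1 and 0 immune, 0 and 0 endothelial and 4 and 3 islet genes rose and fell. Camera adjusted p was 0.902, 0.681, 0.684 and 0.895 for the 4 lists. Median and mean differed in sign for the fibroblast list (0.17 and -0.00398), the endothelial list (-0.0836 and 0.0155) and the islet list (-0.0951 and 0.00556). CAF_CM replicate 2 stood apart from replicates 1 and 3 in the mean log2 difference from control of the fibroblast (0.21 against -0.0393 and -0.18) and endothelial lists (0.15 against -0.0125 and -0.0937), with Fbln2 at 1019 against 657 and 705 normalized counts. The Fbln1 call was lost with library totals (adjusted p = 0.0911), in DESeq2 (0.0955) and without control replicate 1, 2 or 3 (0.0765, 0.115 and 0.0902), and that of Dcn without control replicate 3 (0.0670). Plvap was lower past the threshold in several settings (adjusted p = 0.0454 in edgeR, 0.0137 without CAF_CM replicate 1 and 0.0359 without control replicate 2), as was Tek (0.0198 without CAF_CM replicate 2 and 0.0482 without control replicate 2).

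The 3 genes with the highest mean level were pseudogenes that resemble mitochondrial genes, and all 3 fell. Gm28661 went from 146272 ± 13896 to 68988 ± 6008 normalized counts, Gm10925 from 141133 ± 15038 to 73818 ± 5641 normalized counts and Gm29216 from 122301 ± 9405 to 56392 ± 656 normalized counts, falls of 2.12, 1.91 and 2.16 times (adjusted p of 4.06e-05 or less). Gm28661 and Gm10925 are 100% and Gm29216 is 99.8% identical over the match to a transcript of the mitochondrial genome, so reads of the mitochondrial transcript and of the nuclear copy cannot be told apart and the separate values are uncertain.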

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

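The pseudocount, TMM scaling, group weight and length and GC settings were chosen after seeing the data, as was running the planned edgeR test on recovered reads. Of the 92 named genes called, 87 kept their call and all kept their direction in every alternative run. They were largely picked from these data by fold change or adjusted p, so they say little on the other called genes. Of all 5555 genes called, 3506 were called in the same direction without control replicate 1, 3640 without control replicate 2 and 3774 without control replicate 3. With the length and GC correction, which tested fewer genes, 4608 were. The effect of depth was not tested. Genes at least 2-fold higher and lower numbered 115 and 399 with no filter, where more genes were tested, and those lower numbered 139 with a filter of 1 CPM, which tests fewer low genes, and 146 with a pseudocount of 5, which shrinks low genes. Leaving out 1 library gave 1868 to 3509 higher and 1659 to 2943 lower genes, 64 to 119 and 214 to 318 by 2-fold or more, and values of -0.42 to -0.0484 for Lama5 and -0.0488 to 0.27 for Cpa1. Lama5 was -0.38 with the length and GC correction. The cause was not tested.

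The acinar enzyme list kept its median of -0.39 and lost its call with an estimated correlation, where the correlation alone changed. Besides the acinar enzyme and ductal lists, 3 lists were called in the main test, 0 with an estimated correlation, 7 by fry, 6 without a filter, 5 with the length and GC correction and 2 to 6 with 1 library left out. Among lists not called in the main test, the direction of the test changed in these settings, with these medians: islet markers with library totals (-0.14) and by fry (-0.0951), acinar regulators in DESeq2 (0.15), immune markers without a filter (-0.28), stemness at 1 CPM (-0.0497), mesenchymal genes with the length and GC correction (0.0274) and immediate early genes by fry (0.0504). Fibroblast markers turned in DESeq2 (0.16), without a filter (-0.10), at 1 CPM (0.13), with group weights (0.17) and with the length and GC correction (0.15). The direction also turned with 1 library left out, where medians ran from -0.43 to -0.0569 for laminins, -0.00199 to 0.0651 for mesenchymal, -0.0440 to 0.0395 for stemness and 0.0315 to 0.22 for fibroblast markers. The median alone changed sign for islet markers (-0.12 to 0.0117), and endothelial markers kept both (-0.14 to -0.0331). The cause was not tested.

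The replicate block moved the counts to 3166 higher and 2755 lower genes and left the fibroblast median at 0.17 with its direction by camera turned. Deviations of same-numbered libraries from their group means correlated across genes at 0.0703, 0.0291 and 0.0305, each the highest for its pair but none above 0.1, so the numbers were not taken to pair the libraries. The block changed the call of 1 named gene, Plvap (adjusted p = 0.0221).

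For the counts of higher and lower genes, 1 of the 10 splits of the 6 libraries into 3 and 3 gave as many genes, the real one, with 2953 and 2602, and the highest of the others gave 0. With 10 splits, the share cannot fall below 0.1.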

Other observations

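The comparison of pseudogenes, the tests of the spread within groups, the scan of symbol families, the length and GC correction and the comparison of nuclear mitochondrial genes with the copies were chosen after the results had been seen, and the neuronal pattern was noticed in the fold changes before its tests were set.

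Families of genes that share the start of a symbol were compared with all other genes, 79 families of at least 15 members in all. The start is the letters before the first digit, so a family can hold regulators and pseudogenes beside the genes it is known for. Solute carriers had the lowest p, with 82 of 243 Slc genes lower and 22 higher (camera adjusted p = 1.34e-04). Of 23 cytochrome P450 genes (Cyp), 11 fell and 1 rose (adjusted p = 0.00787). Among rising families was Eif, the start used for translation initiation factors, with 21 of 59 higher and 1 lower (adjusted p = 0.00127). Another was Rab, the start used for small GTPases of vesicle traffic, with 25 of 66 higher and 3 lower (adjusted p = 0.0101). None of these calls held with an estimated correlation (adjusted p = 0.569 for Slc, Cyp and Rab and 0.655 for Eif).

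Some neuronal genes were among those that rose. Neurod1, Tubb3, Draxin, Syt1, Hpca, Nefm, Nefl and Elavl2, picked by their fold changes, had log2 fold changes of 0.83 to 2.05 (median 1.37). A hypothesis is that a broader set of neuronal genes rose. A list of 62 other neuronal genes, written without looking up their values, was higher (limma's camera, p = 3.33e-07; p = 4.13e-05 after correction for length and GC content; p = 0.0987 with an estimated correlation), with a median log2 fold change of 0.21 (0.18 after that correction) and 29 members higher, including Rbfox3 (1.16), Dcx (0.68), Elavl3 (0.68) and Crmp1 (0.54), and 2 lower, Cplx2 and Scg3. Correcting each library for transcript length and GC content left the median of the 8 genes at 1.38. That correction moved the genes tested by a median of 0.0764 log2 units, and the 8 genes were picked for their large changes. It could hardly have taken these away, so the test shows only that a trend shared by all genes is smaller than these rises. The exposure to conditioned medium remains open beside any other difference between the groups.

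Pseudogenes that resemble mitochondrial genes fell, as all 11 tested copies at least 95% identical to a mitochondrial transcript were lower, and their share of reads was 2.97 ± 0.238% in control and 1.36 ± 0.0804% in CAF_CM libraries (mean ± SD, n = 3). Their median log2 fold change lay -1.15 from that of 1753 other pseudogenes, whose median was 0.0481, so the fall was not one of pseudogenes in general. Since this contrast was set after the copies were seen to fall, it cannot decide whether reads of mitochondrial transcripts were counted at nuclear copies. Nuclear genes of the respiratory chain and mitochondrial ribosome had a median of -0.0904 (44 of 159 lower, 4 higher; bootstrap SE of the median 0.0148; camera p = 6.73e-06, and 0.397 with an estimated correlation), and -0.0242 after correction for length and GC content (camera p = 0.0298). A fall as large as that of the copies is argued against, since their median was 0.0824 of that of the copies, under a bound of 0.5 set after these values were seen; a smaller fall stays undecided, as the uncorrected median missed the bound of -0.1 set beforehand by less than its SE, which was added after the value was seen, and the corrected median missed it by more. A lower level of mitochondrial RNA and a difference in its capture in library preparation remain open.

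CAF_CM libraries varied more than control libraries: library 2 differed from 1 and 3 in targets of the hypoxia response such as Slc16a3 (2712 against 1373 and 1162 normalized counts), and library 1 from 2 and 3 in Hipk2 (821 against 1709 and 1669). A single aberrant library is argued against, as the least variable CAF_CM pair varied 2.42 times as much as the most variable control pair. The SD beyond sampling error in CAF_CM libraries was 0.121 before and 0.105 after removal of a trend with length and GC content. In control libraries it was 0.0366 before and 0.0317 after. The ratio of CAF_CM to control was 3.31 before and 3.32 after, so by this measure the trend did not account for the excess over controls. That measure replaced an SD ratio that included sampling error, after the latter gave 1.69 (1.83 before correction), between the bounds of 1.5 and 2 and so undecided. A share of 0.00604 of the variance within CAF_CM lay along the mean difference from control. That argues against 1 response scaled alike over all genes, but cannot decide on a response carried unequally by some of them. In replicates 1, 2 and 3 the hypoxia list lay at -0.46, -0.0475 and -0.54 and the interferon list at -0.38, -0.41 and -0.46. Different extents of the response in part of the genes stay open. Over genes with at least 100 reads in a pair, variance between control replicates 2 and 3 was 1.24 times that of sampling. It was 2.25 and 2.76 times for the other control pairs and 7.80 to 14.3 times within CAF_CM. Whether treated libraries came from separate cultures and controls from 1 is not stated and stays open.

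Counts at Lars2, Gm15564 and Mir6236 varied within both groups and largely in parallel. Lars2 had 14295, 19737 and 20008 normalized counts in control and 22316, 28539.9 and 12432 in CAF_CM replicates 1, 2 and 3. Gm15564 had 3494, 4979 and 4876 in control and 5429, 7412 and 3012 in CAF_CM, and Mir6236 1685, 2050 and 2025 in control and 2263, 2826 and 1201 in CAF_CM. Whether these reads came from transcripts of the named genes was not tested.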
